A study of Homo sapiens with 6 samples.

How the data were processed

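RNA came from MCF-7 cells stably expressing eGFP-LC3, reverse transfected with siRNA against DRAIC or with a control siRNA at 10 nM; medium with 6% serum was renewed after 24 h and cells were taken at 72 h, per the labels' protocols. There were 3 biological replicates of each group. Ribosomal RNA was removed with a Ribo-Zero kit, TruSeq libraries were made and sequenced on a NextSeq500 instrument, per the labels' protocols. The submitters' processing notes name cutadapt, Bowtie2 2.2.4, HTSeq and the hg19 build; their settings, the gene annotation and whether counting used strand are not given in the sources used here. Reads shared by overlapping or antisense genes, or by near-identical copies, may therefore be assigned either way.

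The authors deposited a table of raw read counts per gene for the 6 libraries, with 26215 genes, of which 8298 had a count of 0 in every library. Totals ran from 5657270 to 13511784 counts. The authors also deposited a table of their own comparison. Per the file headers it holds a mean normalised count, a log2 fold change with its standard error, a test score (headed as a statistic), and a p-value with its adjusted p-value. The tool behind it is not given in the sources used here. The mean normalised counts equalled those from DESeq2 size factors on the deposited counts, with a largest relative difference of 4.88e-15.

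Genes were named as in the files, and DRAIC was matched to LOC145837 by its RefSeq gene number. Because the files use hg19 and the reference annotation used here (GENCODE, with RefSeq names) is of a later build, that annotation served only for names, neighbouring genes, transcript length, GC content and 3' UTR sequence, and coordinates are left out.

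Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (a minimum count of 10 and a total of 15), and the quasi-likelihood F-test of DRAIC siRNA against control siRNA, two-sided, with Benjamini-Hochberg adjustment over 12515 genes and a threshold of 0.05. These genes held over 99% of the counts of every library. The standard error of a log2 fold change was taken from the fold change and its F statistic. CPM values use TMM library sizes. The RNase P RNA RPPH1 took 10.4% (exact binomial 95% interval 10.4 to 10.4) to 14.5% (14.5 to 14.6) of a library's counts, and the 10 most abundant genes 15.2% to 19.1%. Such intervals cover counting error only. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.46 to 9.93, so no libraries were merged. The common dispersion gave a biological coefficient of variation of 8.02%. The first principal component held 47.4% of the variance and separated the groups.

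The 24 gene lists (autophagy machinery and receptors, lysosome, mTORC1 and AMPK signalling, oestrogen-induced, luminal, basal and mesenchymal, G1/S, G2/M, p53, stress response, interferon, NF-kB, cholesterol, fatty acid, glycolysis and hypoxia, histones, ribosomal proteins, respiratory chain, immediate early, silencing machinery, and 3 lists of markers of other cell types), the tests and their design, and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and alternatively with an estimated correlation and with fry. The estimated correlation rests on only 6 libraries, so failing that alternative does not show that correlation removed a call. camera compares a list with all other genes; fry asks whether the list's own genes move one way. The named genes are DRAIC, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, up to 4 called members of each list with the smallest adjusted p (the member with the smallest p where none was called), and the 3 most highly expressed called genes. Not every gene the rule takes is described. MAP1LC3B was added after its values were seen, because of the reporter.

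The alternatives were DESeq2 size factors, total counts alone, no low-count filter, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, robust dispersions, the replicate number as a block, removal of smooth GC content and length trends by offsets (97.8% of tested genes have both values), and leaving out each library in turn. Thinning every library to the lowest total, and list tests under total counts, were added after seeing the data. The edgeR test was tested on simulated counts with 12423 genes and the real library sizes: 72 of 99 genes changed 1.5-fold (72.7%) and 94 of 100 changed 2-fold (94%) were recovered, with 11 unchanged genes called. In the camera list test on 12515 simulated genes, a list of 40 members, some of them raised 1.5-fold, gave a camera p of 1.48e-35, and a list of 40 unchanged genes a camera p of 0.42. The simulated genes were drawn independently of each other, so this check does not cover lists whose genes are correlated. The 3' UTR search used, for each gene, the transcript with the longest coding sequence, and covered the 11028 tested genes (88.1%) whose 3' UTR had at least 50 bases. Each 7-mer present in at least 50 genes was tested on the residuals of log2 fold change after regression on 3' UTR length, base composition and expression. With fold changes permuted over these 11028 genes, a planted 7-mer with a shift of -0.15 ranked 1. That search and the figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.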

Results

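Total RNA was profiled in MCF-7 cells, an established line of oestrogen receptor-positive luminal breast cancer cells, that stably carried eGFP-LC3, a fluorescent form of the autophagosome protein LC3. Cells received 10 nM of an siRNA against the long non-coding RNA DRAIC or a control siRNA for 72 h, with 3 biological replicates of each, giving 6 libraries in 2 groups. Ribosomal RNA was depleted, so transcripts without a poly(A) tail, such as histone mRNAs and small structured RNAs, were also counted. Total counts were 10851767, 5657270 and 8179230 in control siRNA replicates 1 to 3 and 9269200, 11725077 and 13511784 in DRAIC siRNA replicates 1 to 3. The comparison asks which transcripts differ in level when DRAIC is lowered in these cells.

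DRAIC, listed in the files as LOC145837 and located on chromosome 15, was lower in all 3 DRAIC siRNA libraries than in any control library. Its level was 2.39 ± 0.476 CPM with control siRNA and 0.116 ± 0.0490 CPM with DRAIC siRNA (mean ± SD, n = 3), a log2 fold change of -4.20 ± 0.47 (SE) with an adjusted p of 9.78e-06 by edgeR. The control libraries held 22, 17 and 17 DRAIC reads and the DRAIC siRNA libraries 1, 2 and 1. From the pooled 56 and 4 reads, the level left was 4.96% of the control level, with an exact 95% interval of 1.31% to 13.4% that covers counting error only. DRAIC was a low-count RNA in these libraries, with 17 to 22 reads in each control library. Only 2.46% of the tested genes had a lower mean over all 6 libraries, a mean that the DRAIC siRNA libraries pull down. The exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow.

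**Figure D1:**
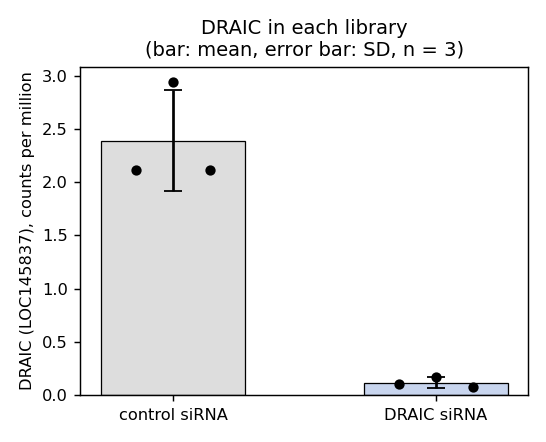
DRAIC level in CPM (vertical axis) in the control siRNA and DRAIC siRNA groups; points are libraries, bars are means and error bars are SD of 3 libraries. The mean was 2.39 CPM with control siRNA and 0.116 CPM with DRAIC siRNA, and no DRAIC siRNA library reached the lowest control library.

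Among the genes with a mean of at least 1 CPM that rose most were ITGB6, the beta subunit of an integrin that activates latent TGF-beta, PDK4, a kinase that inhibits pyruvate dehydrogenase, and ST3GAL5, the enzyme that makes the ganglioside GM3. ITGB6 went from 11.1 ± 1.11 to 46.2 ± 4.44 CPM (SD, n = 3), 4.21-fold, and ST3GAL5 from 4.31 ± 1.18 to 17.1 ± 2.06 CPM, 3.81-fold. PDK4 rose 3.93-fold from 0.419 CPM, and the zinc finger gene ZNF175 rose 4.96-fold from 1.66 CPM. At that level the falls were led, after DRAIC itself, by MAP2K6, a kinase that activates p38, with a log2 fold change of -2.27 ± 0.39 (SE), and by BTN3A1 (-1.72), a butyrophilin recognised by gamma-delta T cells. MAP2K6 and BTN3A1 were left at only 0.469 and 0.602 CPM with DRAIC siRNA. NR2F1, an orphan nuclear receptor, fell by 1.56 on the log2 scale and VASH2, a vasohibin, by 1.46. The fatty acid elongase ELOVL2 went from 48.7 ± 1.70 to 20.1 ± 1.78 CPM (SD, n = 3), with an adjusted p of 3.15e-07 by edgeR.

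Other large rises were those of LOC102724550 (log2 fold change 2.46), ZCCHC12 (2.41), the GABA-B receptor subunit GABBR2 (1.93) and ZNF365 (1.90). Their control means were only 0.365, 0.285, 0.801 and 0.612 CPM, so the sizes of these rises rest on few reads. The remaining falls were KCNIP3 (-1.38, to 0.845 CPM), the U6 spliceosomal RNA copy RNU6-2 (-1.34), the mitochondrial carrier SLC25A48 (-1.28) and the Wnt ligand WNT2B (-1.24). RNU6-2 has near-identical copies in the genome and BTN3A1 has close paralogs, so their counts are uncertain. The call of KCNIP3 was lost without control siRNA replicate 3 (edgeR adjusted p 0.0536) and that of RNU6-2 under a robust dispersion fit (edgeR adjusted p 0.161). The 3 most highly expressed genes that changed all fell: RMRP, the RNA of a mitochondrial and nucleolar ribonuclease, by 0.43 on the log2 scale, NUCKS1, a chromatin-associated protein, by 0.57, and FAM102B by 0.48.

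**Figure D2:**
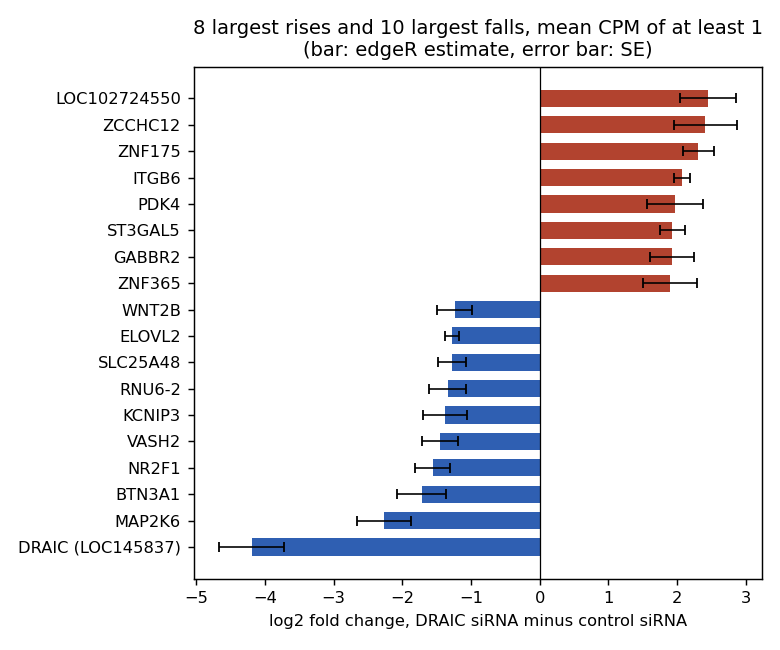
The 8 largest rises and 10 largest falls among genes past an adjusted p of 0.05, with a mean of at least 1 CPM and groups that did not overlap; bars are edgeR log2 fold changes (horizontal axis, DRAIC siRNA minus control siRNA) and error bars are SE from 3 libraries per group. Rises run from 1.90 for ZNF365 to 2.46 for LOC102724550 and falls from -1.24 for WNT2B to -4.20 for DRAIC.

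Across the 12515 genes tested, 1793 (14.3%) changed at an adjusted p under 0.05 by edgeR, 947 upward and 846 downward. With a change of at least 1.5-fold as well, 521 remained, 357 up and 164 down, and 164 changed at least 2-fold, 127 up and 37 down. The median size of a called change was 0.45 on the log2 scale. The groups did not overlap in 32.0% of tested genes, against 10% by chance with 3 and 3 libraries. Under scaling by total counts alone, 1595 genes were called, of which 64.9% rose, against 52.8% with TMM scaling. The count fell to 1037 without control siRNA replicate 3, to 1156 without DRAIC siRNA replicate 1 and to 982 without DRAIC siRNA replicate 2, and it was 2767 after GC content and length trends were removed.

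Genes of autophagy and of the lysosome were the groups closest to the eGFP-LC3 reporter. Of 45 measured genes of the autophagy machinery, 4 rose and 2 fell (5 and 2 when adjusted over the list alone). Over all tested genes 14.3% were called, and the counts of each list are to be read against that share. The share of the machinery genes that were called was no higher. WIPI1, which binds PI3P on forming autophagosomes, went from 36.4 ± 2.27 to 61.7 ± 4.82 CPM (SD, n = 3), with an adjusted p of 3.78e-05 by edgeR. ATG16L1, part of the complex that attaches LC3 to membranes, rose by 0.39 on the log2 scale and ZFYVE1, a marker of the sites where autophagosomes form, by 0.54, while TMEM41B, a scramblase of the endoplasmic reticulum, fell by 0.33. Each of these last 3 calls was lost when 1 library was left out: ATG16L1 without control siRNA replicate 3 (edgeR adjusted p 0.0595), ZFYVE1 without control siRNA replicate 1 (0.0510), and TMEM41B without control siRNA replicate 3 or DRAIC siRNA replicate 2 (up to 0.0968). MAP1LC3B itself was at 21.0 ± 3.05 and 25.1 ± 7.72 CPM, a difference within the replicate spread (edgeR adjusted p 0.29); whether reads of the transgene were counted under an LC3 gene is not given in the sources used here. The machinery list had a median log2 fold change of 0.10. Its adjusted p was 0.0494 by camera, 0.0439 by fry, and 0.38 by camera with an estimated correlation. The camera call was also lost with the replicate number as a block (camera adjusted p 0.05). It was lost too without control siRNA replicate 1 (camera adjusted p 0.0597), control siRNA replicate 3 (0.128) or DRAIC siRNA replicate 1 (0.114).

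Of 20 measured autophagy receptors, 5 rose (9 rose and 2 fell when adjusted over the list alone). CCPG1 and FAM134B, receptors for the turnover of endoplasmic reticulum, rose by 0.70 and 0.59 on the log2 scale, and the ubiquitin-binding receptor TAX1BP1 by 0.33 and the mitochondrial receptor FKBP8 by 0.31. Without control siRNA replicate 2, TAX1BP1 was no longer called (edgeR adjusted p 0.0611); FKBP8 lost its call in 4 of the runs that left out a library (up to 0.167). The receptor list had a median of 0.15 and an adjusted p of 0.0167 by camera and 0.0439 by fry. Its adjusted p by camera was 0.38 with an estimated correlation, and 0.0608 without control siRNA replicate 2. Of 58 measured lysosomal genes, 13 rose and 1 fell (18 and 3 when adjusted over the list alone). The sialidase NEU1 went from 79.9 ± 7.44 to 134 ± 14.3 CPM (SD, n = 3) and the protease CTSL from 36.2 ± 0.748 to 58.3 ± 7.68 CPM. TFEB, a transcription factor for lysosomal genes, rose from 1.33 ± 0.181 to 3.82 ± 0.463 CPM, a log2 fold change of 1.47, and the lysosomal membrane protein CD63 rose by 0.37. The lysosome list had a median of 0.17 and an adjusted p of 0.00426 by camera, 0.0674 by fry, and an adjusted p of 0.38 with an estimated correlation.

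Of 44 measured replication-dependent histone genes, 36 fell (41 when adjusted over the list alone), with a median log2 fold change of -0.40. HIST1H4D went from 582 ± 50.4 to 354 ± 24.0 CPM (SD, n = 3), and HIST1H2BD, HIST1H3B and HIST1H1D fell by 0.57, 0.53 and 0.52 on the log2 scale. Histone genes are near-identical in places, so counts of single members are uncertain. The list had an adjusted p of 5.04e-29 by camera, 0.0203 by fry, and an adjusted p of 0.26 with an estimated correlation. Of 40 measured genes of G2 and mitosis, 18 fell (28 when adjusted over the list alone), with a median of -0.27. CKS2, a subunit of cyclin-dependent kinases, fell by 0.54, the chromosomal passenger protein BIRC5 by 0.48, the cyclin CCNA2 by 0.41 and the kinetochore protein CENPF by 0.47. This list had an adjusted p of 1.14e-12 by camera, 0.0439 by fry, and an adjusted p of 0.38 with an estimated correlation. Of 41 measured genes of DNA replication and the G1/S step, 7 fell and 2 rose (9 and 2 when adjusted over the list alone), with a median of -0.08, an adjusted p of 0.0167 by camera, 0.203 by fry, and an adjusted p of 0.575 with an estimated correlation. The primase PRIM1 and the clamp loader subunit RFC3 fell by 0.47 and 0.45; the licensing factor CDT1 (-0.41) and the thymidine kinase TK1 (-0.35) were called too, but not without control siRNA replicate 3 for CDT1 (edgeR adjusted p 0.0508) and not without control siRNA replicate 2, without DRAIC siRNA replicate 1 or under scaling by total counts for TK1 (up to 0.0587). The camera call of the G1/S list was lost without control siRNA replicate 3 (adjusted p 0.0623) or DRAIC siRNA replicate 1 (0.197).

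Of 33 measured p53 targets, 14 rose and 1 fell (19 and 1 when adjusted over the list alone), with a median log2 fold change of 0.25. CDKN1A, the inhibitor of cyclin-dependent kinases also called p21, went from 163 ± 15.3 to 282 ± 36.3 CPM (SD, n = 3), with an adjusted p of 2.98e-05 by edgeR. The stress cytokine GDF15 rose from 51.2 ± 12.0 to 116 ± 38.4 CPM, a call that a robust dispersion fit did not keep (edgeR adjusted p 0.0877), and C12orf5, the phosphatase TIGAR, rose by 0.71 on the log2 scale. The cyclin CCNG1 moved the other way, with a log2 fold change of -0.55. The list had an adjusted p of 3.66e-07 by camera, 0.0203 by fry, and an adjusted p of 0.26 with an estimated correlation.

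Of 35 measured genes induced by oestrogen, 11 fell and 3 rose (11 and 5 when adjusted over the list alone), with a median log2 fold change of -0.07, an adjusted p of 0.00678 by camera, 0.0660 by fry, and an adjusted p of 0.38 with an estimated correlation. Besides ELOVL2, the chemokine CXCL12 went from 35.2 ± 1.33 to 17.6 ± 1.87 CPM (SD, n = 3), the progesterone receptor PGR from 22.1 ± 1.02 to 13.2 ± 1.12 CPM, and the transcription factor EGR3 from 22.1 ± 1.95 to 11.9 ± 1.11 CPM. Of 27 genes of luminal identity, 3 rose and 4 fell (6 and 4 when adjusted over the list alone). The oestrogen receptor ESR1 went from 547 ± 15.4 to 436 ± 17.9 CPM and the androgen receptor AR fell by 0.43 on the log2 scale, while AGR2, a protein disulfide isomerase of secretory cells, rose by 0.63. The transcription factor TFAP2A had a log2 fold change of -0.78, a call lost without control siRNA replicate 2 or DRAIC siRNA replicate 2 (edgeR adjusted p up to 0.0688). The luminal list did not pass (camera adjusted p 0.97; adjusted p = 0.978 with an estimated correlation), and its median of -0.04 and mean of -0.01 differed in sign from its test, which pointed up. Of 30 basal and mesenchymal genes 12 were measured, of which 3 rose and 3 fell (3 and 3 when adjusted over the list alone). Their list had an adjusted p of 0.0117 by camera, 0.0987 by camera without control siRNA replicate 1, and 0.0731 by fry. With an estimated correlation the adjusted p by camera was 0.431. The test pointed up, but the median log2 fold change was 0.13 and the mean 0.33, pulled up by ITGB6 (2.07). ITGB6 and the matrix protein TGFBI (0.94) rose, whereas fibronectin FN1 (-0.33) and TP63, a transcription factor of basal cells (from 3.28 ± 0.630 to 1.68 ± 0.744 CPM, SD, n = 3), fell. FN1 and TP63 were each no longer called without control siRNA replicate 1, control siRNA replicate 3 or DRAIC siRNA replicate 2, nor FN1 without DRAIC siRNA replicate 1 (edgeR adjusted p up to 0.123 for FN1 and 0.139 for TP63), and TP63 was lost under scaling by total counts and in DESeq2 as well.

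Of 26 immediate early genes, 11 rose and 3 fell (11 and 3 when adjusted over the list alone), with a median log2 fold change of 0.12. The zinc finger factor EGR1 went from 10.2 to 19.6 CPM, a log2 fold change of 0.95 ± 0.15 (SE, n = 3), and DUSP6, a phosphatase that acts on ERK, from 2.61 ± 0.119 to 7.26 ± 2.58 CPM (SD). IER2 rose by 0.50, while EGR3 fell by 0.89. The list had an adjusted p of 0.0167 by camera, 0.115 by fry, and an adjusted p of 0.523 with an estimated correlation; the camera call was lost without control siRNA replicate 1 (adjusted p 0.106) or DRAIC siRNA replicate 1 (0.103).

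Lists of energy metabolism and the ribosome had small positive medians. Of 33 genes of glycolysis and hypoxia, 6 rose (10 rose and 3 fell when adjusted over the list alone), among them the prolyl hydroxylase P4HA2 (0.63), pyruvate kinase PKM (0.39), enolase ENO2 (0.75) and hexokinase HK1 (0.36). That list had a median of 0.13, an adjusted p of 0.0130 by camera, 0.0439 by fry, and an adjusted p of 0.38 with an estimated correlation. Of 50 nuclear-encoded respiratory chain genes, 9 rose (9 when adjusted over the list alone), including UQCRB (0.54), SDHA (0.56) and ATP5A1 (0.39), parts of complexes III, II and V. Their median was 0.07, with an adjusted p of 0.0150 by camera, 0.143 by fry, and an adjusted p of 0.575 with an estimated correlation. Of 71 cytosolic ribosomal protein genes, 7 rose and 2 fell (5 and 1 when adjusted over the list alone), with a median of 0.09, an adjusted p of 0.00574 by camera, 0.275 by fry, and an adjusted p of 0.601 with an estimated correlation. The share of ribosomal protein genes that were called was no higher than the 14.3% of all tested genes. RPS27 and RPL3 rose by 1.06 and 0.50 on the log2 scale. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Without control siRNA replicate 3 both the respiratory and the ribosomal lists lost their calls (camera adjusted p 0.132 and 0.293), as they did without DRAIC siRNA replicate 2 (0.137 and 0.0584).

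Lists of lipid synthesis and nutrient signalling did not pass the list test with all 6 libraries. In the fatty acid list and the mTORC1 and AMPK list, the share of genes called was no higher than the 14.3% of all tested genes. Of 24 cholesterol synthesis genes, 4 fell (4 when adjusted over the list alone): the sterol sensor partner INSIG1 (-0.46), the transcription factor SREBF2 (-0.44), mevalonate kinase MVK (-0.41) and the sterol carrier STARD4 (-0.44). STARD4 lost its call in 6 of the alternatives (edgeR adjusted p up to 0.147), 4 of which left out a library: control siRNA replicate 1 or 3, or DRAIC siRNA replicate 1 or 2. The list's median of 0.01 differed in sign from its mean of -0.08 and its test, which pointed down (camera adjusted p 0.0910, or 0.0424 without control siRNA replicate 2; adjusted p = 0.431 with an estimated correlation). Of 22 fatty acid synthesis genes, 2 rose and 1 fell (2 and 1 when adjusted over the list alone); acetyl-CoA carboxylase ACACB fell by 0.47, while the acyl-CoA synthetase ACSL3 (0.29) and the desaturase SCD5 (0.29) rose, both calls lost without DRAIC siRNA replicate 1 or 2 (edgeR adjusted p up to 0.119 and 0.126), and the list had a camera adjusted p of 0.495. Of 41 genes of mTORC1 and AMPK signalling, 2 rose and 3 fell (2 and 3 when adjusted over the list alone); the stress-induced mTORC1 inhibitor SESN3 rose by 0.53 on the log2 scale. MLST8, a subunit of mTOR complexes, the GATOR1 subunit NPRL3 and the translation repressor EIF4EBP1 fell by 0.36, 0.53 and 0.43, all no longer called without DRAIC siRNA replicate 2 (edgeR adjusted p up to 0.0661, 0.0861 and 0.0792 over the alternatives), and the list had a camera adjusted p of 0.862.

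Stress, immune and silencing lists did not pass by camera with all 6 libraries either. Of 38 genes of the integrated stress response and the unfolded protein response, 5 rose and 5 fell (5 and 5 when adjusted over the list alone). The cystine transporter SLC7A11 fell by 0.98 on the log2 scale and the mitochondrial folate enzyme MTHFD2 by 0.39, while the endoplasmic reticulum protein CRELD2 rose by 0.52. The list's median of -0.01 and mean of -0.02 differed in sign from its test, which pointed up (camera adjusted p 0.98). Of 27 interferon-stimulated genes, 1 rose (1 when adjusted over the list alone), BST2, which tethers enveloped viruses, by 0.60, with a camera adjusted p of 0.275 for the list. Of 18 NF-kB targets, 2 rose (2 when adjusted over the list alone), RELB (1.45) and ICAM1 (0.67), with a camera adjusted p of 0.563 for the list. RELB and ICAM1 lost their calls in 5 and 6 of 16 alternatives, with control siRNA replicate 3 and DRAIC siRNA replicates 1 and 2 among the libraries whose omission did so for both (adjusted p up to 0.170 by edgeR for RELB and 0.161 by DESeq2 for ICAM1). Of 14 genes of the small RNA silencing machinery, 2 fell (2 fell and 1 rose when adjusted over the list alone): PRKRA, a partner of Dicer, by 0.35 and DICER1 by 0.30. PRKRA was not called without DRAIC siRNA replicate 2 (edgeR adjusted p 0.0693), nor DICER1 without control siRNA replicate 1 or 3 or DRAIC siRNA replicate 1 or 2 (up to 0.122), and the list had an adjusted p of 0.0762 by camera, 0.0385 by camera without DRAIC siRNA replicate 3, 0.0462 by fry, and an adjusted p of 0.380 with an estimated correlation.

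Markers of other cell types were scarce. Only 3 fibroblast and stromal markers, 2 leukocyte and endothelial markers and 4 markers of other cancer lines had enough reads to be tested, with camera adjusted p of 0.0551, 0.497 and 0.220. The fibroblast and stromal markers had a median log2 fold change of 0.63, all 3 positive, and their list passed without control siRNA replicate 2 (camera adjusted p 0.0133) or DRAIC siRNA replicate 2 (0.0423), against an adjusted p of 0.461 with an estimated correlation and all libraries. The collagen gene COL5A1 rose from 8.60 ± 1.70 to 13.1 ± 1.05 CPM and the tubulin gene TUBB3 from 25.9 ± 1.66 to 33.7 ± 4.61 CPM (SD, n = 3); adjusted over the list alone, 1, 0 and 3 markers of these lists were called. COL5A1 was not called without control siRNA replicate 1 or 3 (edgeR adjusted p up to 0.0675), and TUBB3 lost its call in 5 of 16 alternatives (up to 0.205), among them those without control siRNA replicate 1 or 3 and without DRAIC siRNA replicate 1 or 2.

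**Figure D3:**
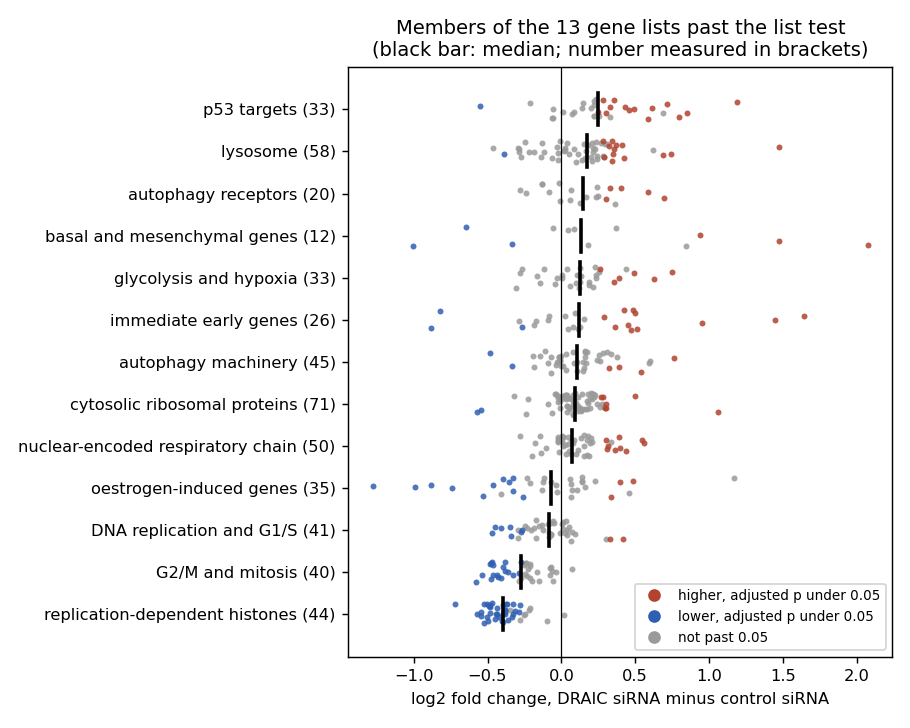
Log2 fold change (horizontal axis, DRAIC siRNA minus control siRNA) of each measured member of the 13 gene lists past an adjusted p of 0.05 by camera; points are genes, coloured by call, and black bars are list medians. Medians run from -0.40 for histones to 0.25 for p53 targets, and 0 of the 13 lists passed with an estimated correlation between genes.

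Of the 24 lists, 13 passed the camera test, 9 upward and 4 downward, at its preset correlation of 0.01. With a correlation estimated from the 6 libraries, 0 passed, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.26. By fry 7 passed. The estimated-correlation alternative was strict even where correlation was low. The autophagy machinery had an estimated correlation of 0.0169, near the preset 0.01, yet its adjusted p by camera went from 0.0494 to 0.38. For a list like this, failing that alternative therefore does not show that correlation between genes accounts for the call. The estimate was 0.0601 for p53 targets and 0.0615 for the lysosome list. It was higher for others that passed, such as 0.401 for ribosomal proteins, 0.306 for histones and 0.268 for G2/M and mitosis. The small camera p-values of these lists rest on the preset 0.01, and how far correlation accounts for them stays open.

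The authors' deposited table listed 12833 genes, of which 1365 had an adjusted p under 0.05, 706 up and 659 down. Of these, 1345 (98.5%) were also called by edgeR here, all in the same direction. Across the 12514 genes in both, which are not independent replicates, the fold changes had a Spearman's rho of 0.987. Fold changes in the authors' deposited table were smaller, with a median ratio of 0.868 to those computed here. For DRAIC the authors' deposited table gives a log2 fold change of -0.89 with an adjusted p of 1.24e-06, against -4.20 by edgeR here. The gap was also wide for the low-count gene PDK4 (0.46 against 1.97) and narrow for the highly expressed NUCKS1 (-0.54 against -0.57). These estimates are therefore not like measures at low counts, and -0.89 should not be read as the fraction of DRAIC left. How the authors' fold changes were estimated is not given in the sources used here.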

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

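DRAIC stayed lower under all 16 alternatives, from -4.55 to -3.92 on the log2 scale over the libraries left out, and 0 called results changed direction; the fold changes of some genes that were not called did, such as MAP1LC3B (-0.01 to 0.41). Thinning and list tests under total counts were chosen after seeing the data. The count of changed genes (1793) was 2767 with GC content and length trends removed, 2768 with that removal and the replicate block, and 982 to 1827 over the libraries left out; the cause was not tested. Genes called with at least 1.5-fold change ranged from 416 to 565 over the libraries left out, and called list members (197) from 119 to 202. Of the gene list tests 13 passed, 0 with an estimated correlation, where 2 had an unadjusted p under 0.05 by camera, 7 by fry and 9 to 14 over the libraries left out. With an estimated correlation the adjusted p by camera was 0.38 for autophagy machinery, lysosome, oestrogen-induced genes and G2/M and mitosis, and 0.26 for p53 targets and replication-dependent histones. By fry it was 0.0674 for lysosome and 0.0660 for oestrogen-induced genes. It was 0.0439 by fry for autophagy machinery and G2/M and mitosis, and 0.0203 for p53 targets and replication-dependent histones. The autophagy machinery gave 0.05 by camera with the replicate block, which lost its call, and 0.0328 to 0.128 over the libraries left out. The replicate block called 2008 genes by edgeR. Deviations of same-numbered libraries correlated at -0.156, 0.0587 and 0.0598, within the range of differently numbered ones (-0.179 to 0.148). These values gave no sign that the numbers pair the libraries, but with 3 libraries per group they cannot exclude it. For named genes and those chosen after the results were seen, 2188 fold changes kept their side of the threshold, 101 lost it and 13 gained it. Thinned to the lowest total, 1362 genes were called, with 71.0% of the 1793 kept, so depth limits the count. GC correction does not enter camera and was replaced by list counts.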

Other observations

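The genes, short lists and the histone and 3' UTR site tests in this part were chosen after the results were seen; the tests of splits, GC content, DRAIC 7-mers and neighbouring genes were written down earlier. Metallothioneins, small proteins that bind zinc and copper, fell: MT1F went from 9.02 ± 1.54 to 4.45 ± 0.473 CPM and MT1X from 12.1 ± 0.670 to 6.70 ± 0.970 CPM (SD, n = 3), and MT2A fell by 0.52 on the log2 scale. All 3 measured members fell, with an adjusted p of 0.000177 by camera over 4 such lists. With an estimated correlation the adjusted p by camera was 0.0582. These 4 lists were chosen after the fold changes were seen, so their p-values are descriptive and no independent support. MT2A lost its call without control siRNA replicate 3 or DRAIC siRNA replicate 2 (edgeR adjusted p up to 0.0573). Metallothionein genes are similar enough for shared reads. Gelsolin, GSN, which severs actin filaments, rose from 35.6 ± 4.52 to 109 ± 7.64 CPM, and PAPSS2, which makes the sulfate donor PAPS, from 76.4 ± 8.94 to 167 ± 8.04 CPM. The mitophagy kinase PINK1 rose from 26.9 ± 2.78 to 49.6 ± 8.55 CPM and the transcription factor FOXO4 from 16.1 ± 0.355 to 27.0 ± 0.916 CPM. Of 15 measured FOXO targets, 4 rose and 1 fell: the ubiquitin ligase subunit FBXO32 (1.04), KLHL24 (0.77), SESN3 (0.53) and PDK4 (1.97) rose and CDKN1B, which inhibits cyclin-dependent kinases, fell by 0.29 (not called without control siRNA replicate 1 or 3 or DRAIC siRNA replicate 2). That list had an adjusted p of 0.0611 by camera.

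TP53 itself stood at 64.0 ± 1.15 and 67.2 ± 6.14 CPM (SD, n = 3; edgeR adjusted p 0.649), while MDM4, an inhibitor of p53, fell from 303 ± 16.7 to 218 ± 20.1 CPM. Of 11 measured p53 regulators, 1 rose and 2 fell: MDM2 rose by 0.25 and the kinase CHEK2 fell by 0.42, calls lost in 5 and 3 of 16 alternatives, with an adjusted p of 0.355 by camera for the list. The anti-apoptotic gene BCL2 fell by 0.56 and SKP2, a ubiquitin ligase subunit that targets p27, by 0.54. BTN3A2, a paralog of BTN3A1 with similar sequence, went from 1.62 ± 0.537 to 0.324 ± 0.0868 CPM, and 2 of 5 measured BTN2 and BTN3 genes fell (adjusted p 0.0611 by camera). Of the 10 measured genes nearest DRAIC on chromosome 15, 4 were called, PAQR5 (-0.59), UACA (0.32), LARP6 (0.57) and THSD4 (0.45); their median size of change was at the 95.9th percentile of windows of 10 genes, and 5.52% of windows held as many called genes.

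Many genes changed although DRAIC is a low-count RNA. In the 10 ways to split the libraries into 3 and 3, only 1 split, the real one, called as many as 1793 genes by edgeR; the others called 0, with up to 1066 at an unadjusted p under 0.05 against 3535, and a share of 1 in 10 cannot fall under 0.05. GC content or gene length bias accounts for little: 99.3% of called genes kept their call and direction with the trends removed. As to a 3' UTR seed match of a guide against DRAIC, 0 DRAIC 7-mers had a mean shift below -0.1 past Bonferroni correction. The 2 with smaller shifts that passed, the 7-mer with the lowest z of all among them, both occur in DRAIC. The outcomes set down for and against were thus both met, because the outcome for it set no minimum shift. Genes with these 7-mers held 79 more called falls than expected from 3' UTR length, 10.5% of the 754 called falls with a 3' UTR. Direct pairing at these sites would therefore leave most falls unaccounted for. Whether it had a part in some of them stays open, and indirect effects were not tested. Of all tested 7-mers 72.1% occur in DRAIC on either strand and 55.5% on its sense strand, pooled over 20 DRAIC transcripts. AAAAGCA was in 10 of these transcripts. The RefSeq-matched transcript held 1 copy of it, and 7.52% of all 7-mers. No biological explanation was tested.

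Of 44 measured histone genes 36 fell, and lower recovery of short RNAs without poly(A) tails is 1 possible explanation. The 244 measured short RNAs of that kind had a median of -0.116 (95% bootstrap interval -0.162 to -0.0846), against -0.397 (-0.439 to -0.368) for histones. As a class they thus fell by less than the histones. The class was mixed, however, with 23 members called down and 8 up, among them RMRP (-0.43) and SCARNA5 (0.75). All 8 called rises had symbols starting SNORA, SNORD or SCARNA, and so did many called falls. Every called gene with a symbol starting RNU or VTRNA fell, such as VTRNA1-2 (-1.13), VTRNA1-1 (-0.98) and RNU4ATAC (-0.65). RNU6-71P (0.28) and VTRNA1-3 (-0.14) were not called. The class median therefore cannot show how much of the histone fall would be left by lower recovery of only some such RNAs. Fewer cells in S phase remain possible: the G1/S list had a median of -0.0836 (-0.170 to -0.00834), with an adjusted p of 0.575 with an estimated correlation by camera, and the question stays open.

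Genes with AAAAGCA or AAAGCAA in the 3' UTR were slightly lower, by 0.0355 and 0.0397 on the log2 scale, the only 2 of 16134 7-mers past Bonferroni correction for lower fold change. The hypothesis is seed pairing of a guide against DRAIC (guide positions 2 to 8 opposite AAAAGCA, with or without a following A). Genes with the 8-mer AAAAGCAA shifted by -0.0347 relative to genes with a 7-mer site (permutation p 0.001). The 8-mer joins the 2 7-mers that were picked on these same fold changes, which favours a low value for it. This p is therefore not an independent test. The 3429 genes with either site held 329 falls against 250 expected from 3' UTR length, an excess of only 10.5% of the 754 called falls with a 3' UTR. However, genes with only the 6-mer AAAGCA shifted upward by 0.0188 (95% bootstrap interval 0.00303 to 0.0345), which runs against a gradient with site length. Among genes with the 8-mer that fell were ELK4, FAM217B, ZNF395, MDM4 and MAP2K6, though FBXO32 and PAPSS2, which rose, hold the 8-mer too. An A-rich 3' UTR composition stays open: AAAGCAA was picked for the lowest z of all 7-mers, so that 0 of 40 other 7-mers of the same bases were as low was fixed by that choice. The siRNA sequence is not given in the sources used here and a microRNA with this seed was not tested, and the sites were chosen on these fold changes, which favours low values at them, so the pairing stays an open hypothesis.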
